A study of Homo sapiens with 3 samples.

How the data were processed

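H9 human embryonic stem cells gave 3 RNA samples, 1 of polysome-bound RNA, 1 of polysome-unbound RNA and 1 of total RNA, and each was measured on 1 array. Per the labels' protocols, RNA of the polysome pools was purified with a PureLink column kit and total RNA with an RNeasy Plus column kit, and targets were labelled by the manufacturer's standard protocol. How polysomes were separated, and whether cultures were pooled, is not given in the sources used here. Groups were taken from the sample type in the labels.

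The authors deposited log2 expression values, 1 per probe set and array, and the submitters' processing notes name Partek 6.5 and RMA, which subtracts background, normalizes and summarises probes into probe sets. Quantile normalization is the usual RMA step, but the 3 columns do not share a distribution, so the scaling between arrays is unknown. All 33297 values of the bound column end in the same 2 decimals and have 7 decimal digits, against at most 5 in the other columns. From where the fifth decimal is lost at values of 10 and over, a constant between 0.1127 and 0.1140 appears to have been added to the bound column. Its origin is not given, and subtracting its upper bound leaves a median bound minus unbound difference over all probe sets of 0.72, against 0.84 before. The precision is limited by signal over background and by the single array per source.

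Gene names came from the platform annotation that GEO holds. Of the probe sets, 19460 list 1 gene symbol, 1754 list several and 12083 are not listed. Genes were not named from the last 2 kinds. Gene IDs of 19429 probe sets matched a RefSeq table of the assembly GRCh38.p14, which changed 0 symbols and was used for names, gene class and genomic span. No coordinates are given because the sources used here name no build. For the 769 genes with more than 1 probe set, the probe set with the highest mean was kept, which gave 18417 genes. Genes whose mean over the 3 arrays exceeded 3.84, the 95th percentile of the same mean over 480 tissue-restricted genes, entered the comparisons, which left 12057 genes, 11491 of them protein coding.

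Differences are log2 values of 1 array minus those of another. A gene counts as apart at a difference of 1 (2-fold), with no test, because each group has 1 array. Relative differences subtract the difference of the array medians over the 12057 genes. For a gene at or below background on the dimmer array, the fold is given as a lower bound against that array's background level, from the values as deposited. The median of each of 32 gene lists, fixed before the data were examined, was compared with the medians of 10000 random lists of the same size drawn within 20 bins of mean level, and a list was called set apart below percentile 2.5 or above percentile 97.5. Lists with fewer than 5 measured genes are given as values. The list of mitochondrially encoded mRNAs had 0 measured genes. These percentiles describe the 3 arrays, and do not stand in for replicates.

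Named genes were fixed by rule before the data were examined. The rule takes the 12 highest and 12 lowest genes for bound minus unbound and the 5 highest and 5 lowest for each comparison with total RNA, without small RNAs, histones and provisional symbols. It also takes the 2 highest and 2 lowest members of each list described and a fixed set of marker and control genes. GAS5, one of the fixed set, is covered by a probe set with several symbols and is not named for a value here. Of the 12 highest, 2 are not reported here. Genes named outside this rule are marked as such in the closing section, and the markers named for their level in total RNA were picked from the fixed marker lists after their values were seen.

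Alternatives fixed before the data were examined were no level filter or stricter filters, quantile normalization, centring of each array, removal of a lowess trend (span 0.3), the mean of all probe sets of a gene or genes with 1 probe set, thresholds of 1.5-fold and 3-fold, other ways to match or summarise lists, and the 99th percentile of background. Matching on genomic span, matching in 100 bins without the list's own members, and subtraction of the constant were added after the data were seen. Random lists in the comparisons with total RNA, and the alternatives run on them, were added after the data were seen as well. The scripts were tested on simulated data built for bound minus unbound over 12057 genes. With noise of 0.3 (SD, log2), genes planted with a change of 2 were found in 100% after centring, and genes planted with 1.5 in 93.5%. Of 200 simulated lists of 40 genes without a shift, 5.5% fell outside the percentile range. Simulated members were drawn at random, and the SD across genes of the deposited bound minus unbound differences was 0.80. These rates therefore test the scripts and do not carry over to these arrays. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.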

Results

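Gene expression was measured in H9 cells, an established human embryonic stem cell line that was held in conditions that keep it pluripotent. RNA came from 3 sources: polysome-bound RNA, which holds mRNAs that carry several ribosomes, polysome-unbound RNA, which is free of polysomes, and total RNA. Each source was hybridised to 1 Affymetrix human whole-transcript gene array, so there is no replicate check on any difference given here, and no p-value is reported. The median log2 value over all probe sets was 4.96 on the bound array, 4.02 on the unbound array and 4.10 on the total RNA array. On each array the 95th percentile of 480 tissue-restricted genes (olfactory and taste receptors, keratin-associated proteins, defensins), which stem cells are not known to use, served as background. That level was 4.41 for bound, 3.56 for unbound and 3.75 for total RNA, and 64.8%, 63.1% and 64.0% of the 18417 named genes lay above it.

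The total RNA array shows which cell type markers were expressed. Of 40 measured pluripotency genes, 32 were above background in total RNA, among them LIN28A, an RNA-binding protein that blocks let-7 maturation, at a log2 level of 11.10, the stem cell surface protein PODXL at 9.92, SOX2 at 9.50 and the DNA methyltransferase DNMT3B at 9.04. POU5F1 and NANOG are covered by probe sets that list several genes, and they are not named or measured here for that reason. TDGF1, a planned member held under its newer symbol CRIPTO (8.47), was not matched and is left out of all counts of this list. Of 23 germ layer markers 16 were above background, led by KDR at 8.81, and 7 were not. Of 13 trophoblast and amnion markers 8 were above background, led by TFAP2C at 7.08, and of 15 fibroblast markers 13 were, led by COL1A2 at 10.11. The background list itself had 24 of 480 genes above the line by construction. With the 99th percentile of the background list as the line, the counts were 28 pluripotency genes, 6 germ layer, 4 trophoblast and 8 fibroblast markers.

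The comparison of bound with unbound RNA asks which transcripts of these cells are engaged by polysomes. The most bound transcripts included those of the activin receptor ACVR2B (log2 difference 3.83), the actin nucleation factor JMY, the kinase CDC42BPB (3.36) and TTR, the serum carrier of thyroid hormone (3.40). With the small RNA classes described further on left aside, the least bound included RNAs that are not translated, the RNase P RNA RPPH1 (-5.21), the RNase MRP RNA RMRP (-4.31) and the telomerase RNA TERC (-2.54). They also included mRNAs of the zinc finger gene ZNF124 (-2.90), of the ferritin light chain FTL (-2.40) and of ribosomal proteins. These values are the differences as deposited, and they contain an offset between the arrays: over the 12057 genes past the level filter, the bound array's median was 1.26 above that of the unbound array. A relative difference, given from here on, is the log2 difference minus this offset, or the corresponding offset of 1.03 for bound against total RNA and -0.23 for unbound against total RNA. For bound against unbound RNA, a relative difference between -1.26 and 0 is therefore positive as deposited.

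As deposited, 7404 genes were at least 2-fold higher in bound RNA and 188 were lower, so that 97.52% of the genes 2-fold apart were higher in bound RNA. With each array centred on its own median the counts were 767 higher and 1195 lower (39.1% higher). They were 769 and 1125 (40.6%) when the trend of the difference with signal level was removed by lowess, and 1296 and 876 (59.7%) after quantile normalization. Centring and lowess shared 685 of the genes called higher and 1046 of those called lower. The genes of the background list were also higher on the bound array, by a median of 0.71. The direction that most genes take therefore depends on the scaling, and the lists below are described by their distance from random lists of equal size and signal level on the same arrays, which centring leaves unchanged.

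Noncoding RNAs of the splicing and ribosome assembly machinery lay to the unbound side. The 18 measured spliceosomal and other small nuclear RNAs had a median relative difference of -3.21, with 17 of them at least 2-fold lower in bound RNA after centring and 10 as deposited. RNU4-1, the U4 RNA, had a relative difference of -6.13 and RNU2-1, the U2 RNA, -4.69, while RNU5B-1 (-1.38) and RNU5F-1 (-0.98) were closest to the other genes. Among 150 snoRNAs and scaRNAs, the guides of rRNA and snRNA modification, the median relative difference was -1.84. After centring 106 were at least 2-fold lower and 1 was higher, and as deposited 53 were lower and 20 higher. As deposited, SNORD13 was at least 24.3-fold and SNORD13P3 at least 13.9-fold lower in bound RNA, where both were at background. SNORD117 (1.04) and SNORD30 (0.86) lay on the bound side. Both list medians were below those of all 10000 random lists, and they differed from the random lists' median by -3.06 for the small nuclear RNAs and -1.72 for the snoRNAs. Precursors of the microRNA cluster that marks human pluripotent cells followed, with MIR302A at least 10.7-fold and MIR302B at least 7.54-fold lower in bound RNA as deposited.

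Messenger RNAs of ribosomal proteins and other terminal oligopyrimidine mRNAs were on the unbound side. All 58 measured cytosolic ribosomal protein mRNAs were at least 2-fold lower in bound RNA once the arrays were centred, and 42 of the 58 were so as deposited. Their median was -1.33 as deposited and -2.59 relative to the offset, and it differed from that of matched random lists by -2.36 (percentile 0). RPS21 (relative difference -3.45) and RPL10A (-3.39) were lowest, with RPS13 (-3.34) and RPL13 (-3.31) near them, and RPL19 (-1.51) and RPS23 (-1.61) were least affected. The 23 other mRNAs with a terminal oligopyrimidine tract, the 5′ motif that links translation to growth signalling, had a median of -1.96, which differed from random lists by -1.73 (percentile 0). In this list 22 of 23 mRNAs were at least 2-fold lower after centring, and 8 were so as deposited. Among the 22 were TPT1 (-3.06), NOP53 (-3.03) and the elongation factor EEF1A1 (-1.70), and TOMM20 (-0.99) was the exception. Of 38 translation initiation factors 14 were at least 2-fold lower after centring and 2 were higher, EIF3B (1.23) and EIF1AX (1.07). As deposited 3 were lower and 18 higher. The lowest, EIF3L (-2.79) and EIF3F (-2.63), are also in the list of other terminal oligopyrimidine mRNAs. The list of initiation factors as a whole was within the random lists (percentile 5).

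**Figure D1:**
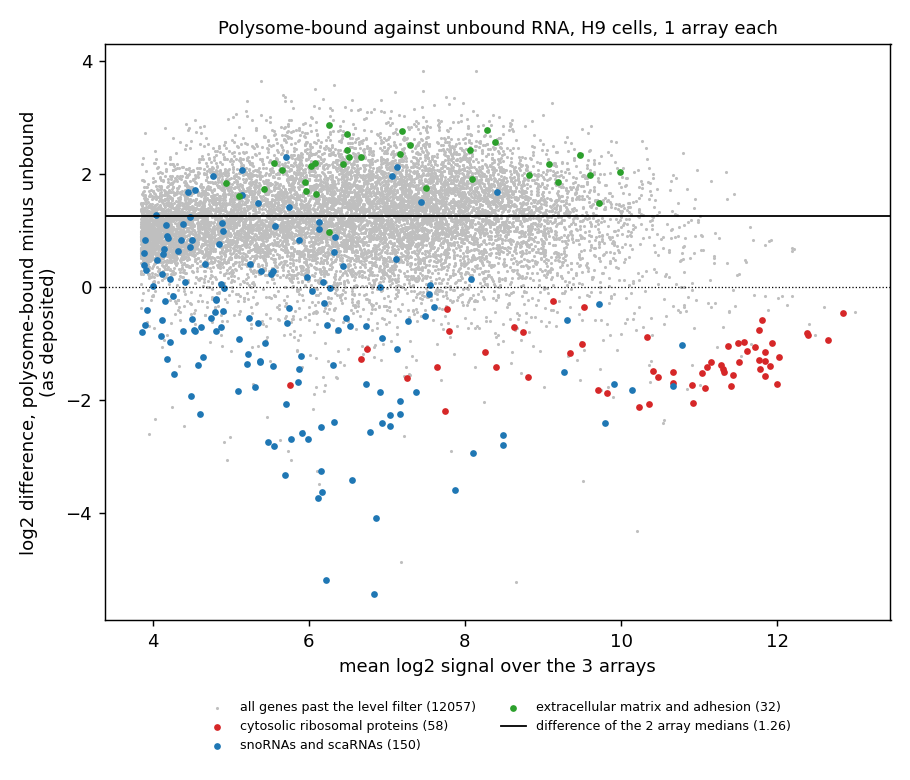
Log2 difference between polysome-bound and unbound RNA (vertical axis, as deposited) against the mean log2 signal over the 3 arrays (horizontal axis), 1 point per gene, with 58 cytosolic ribosomal protein mRNAs in red, 150 snoRNAs and scaRNAs in blue and 32 extracellular matrix and adhesion genes in green. The solid line marks the offset of 1.26 between the array medians, and all ribosomal protein mRNAs lie below it while 31 of the 32 matrix genes lie above it.

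Extracellular matrix and chromatin genes were on the bound side. Of 32 matrix and adhesion genes, 12 were at least 2-fold higher in bound RNA after centring and none was 2-fold lower, with a median relative difference of 0.89 that exceeded random lists by 0.92 (percentile 100). The basement membrane genes NID1 (1.60) and LAMC1 (1.52) were highest, and THBS1 (-0.30) and FN1 (0.22) lowest. Of 44 chromatin remodellers and histone modifiers, 15 were at least 2-fold higher and none lower after centring, with a median of 0.47 that exceeded random lists by 0.46 (percentile 100). CHD3 (2.02), a remodeller of the NuRD complex, and the histone methyltransferase KMT2D (1.90) led this list, and ARID1B (-0.78) and EZH2 (-0.62) were lowest. The list of Nodal, FGF and WNT signalling genes, with ACVR2B (2.56) and the insulin receptor INSR (1.69) at its top and SPRY2 (-1.0) and SPRY4 (-0.92) at its end, exceeded random lists by 0.26 (percentile 97.9). That call was lost under 4 alternatives, with percentiles from 78.7 to 97.3.

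The remaining genes named by rank fall outside these lists. On the bound side they were USF3 (relative difference 2.30), MINDY2 (2.25), RAD54L2 (2.18), KIF27 (2.09), POMK (2.07) and CCDC186 (2.07), and JMY was at least 12.2-fold higher in bound RNA as deposited. On the unbound side they were ZNF124 (-4.16), PLCG2 (-3.61) and ZCCHC18 (-3.56), and the vault RNA VTRNA1-3 was at least 2.45-fold lower in bound RNA as deposited. Further lists were set apart from random lists toward the unbound side, with medians that were positive as deposited and negative after centring. The 411 zinc finger genes of the ZNF series had medians of 0.86 and -0.40, and differed from random lists by -0.33 (percentile 0). After centring 74 of them were at least 2-fold lower and 8 higher, while as deposited 5 were lower and 164 higher. Mitochondrial ribosomal proteins differed by -0.31 (percentile 0.16), from MRPL45 (-1.77) and MRPS35 (-1.51) to MRPL58 (0.86) and MRPS23 (0.78). Mitotic genes differed by -0.35 (percentile 1.46), from TTK (-1.27) and AURKB (-0.80) to CENPE (1.39) and CENPF (1.30). The 41 microRNA precursors, a list that also takes in host transcripts such as MIR600HG (1.76), differed by -0.31 (percentile 0). With random lists matched on genomic span as well as level, the percentiles were 8.83 for mitochondrial ribosomal proteins, 3.23 for mitotic genes and 8.82 for microRNA precursors, so those calls were lost. For microRNA precursors (median span 0.085 kb) the random lists could hold snoRNAs (0.094 kb), small nuclear RNAs (0.143 kb) and the precursors themselves. Their lost call is therefore no test of span. For mitotic genes the difference itself stayed at -0.31 with span matched, and it was -0.072 (percentile 30.8) with the list mean.

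Pluripotency genes were not set apart. Their 32 members past the filter had a median relative difference of 0.01, at percentile 72.2 of random lists, with EPCAM (1.02) and TRIM71 (1.03) highest and OTX2 (-1.06) and MYC (-0.88) lowest. SOX2 had -0.51, LIN28A -0.74 and DNMT3B -0.02, against 0.75, 0.52 and 1.24 as deposited. Nuclear-encoded oxidative phosphorylation subunits were at percentile 30.7, from COX7C (-1.88, also in the terminal oligopyrimidine list) and COX4I1 (-1.66) to NDUFA8 (1.44) and SDHD (1.33). Glycolysis enzymes were at percentile 2.85, with GAPDH at -1.61 and LDHB at -1.42 against PFKL at 1.21 and TPI1 at 1.2. Replication-dependent histones were at percentile 5.72. With span matched they were set apart toward the bound side at 97.8, but those random lists could hold unbound small RNAs, so that call is no check on span. Proteasome subunits (76.1), DNA replication genes (16), aminoacyl-tRNA synthetases (11.8), endoplasmic reticulum chaperones and translocon (96.0), spliceosome and SR proteins (14.3), cytosolic chaperones (13.45), cholesterol synthesis (85.8) and the actin and tubulin cytoskeleton (83.8) were also within the random lists by percentile. The same held for mRNAs with regulatory upstream reading frames (18.5), in which ATF4, a stress-response transcription factor, had -1.36 and ODC1 -1.55. Germ layer (19.2), trophoblast and amnion (59.4), fibroblast (89.5), tissue-restricted background (56.6) and nuclear and other long noncoding RNA lists (17.8) were within it as well, with MALAT1 at -0.11. The long noncoding list also holds RPPH1 and RMRP. It lay below random lists with no filter (-0.54), with the list mean (-1.90) and with genes of 1 probe set (-2.04). Of the snoRNA host list, 3 RNAs were measured, EPB41L4A-AS1 (-3.30), ZFAS1 (-2.90) and TAF1D (-1.88). In all, 3 of the 30 lists with at least 5 measured genes lay above random lists and 8 below.

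**Figure D2:**
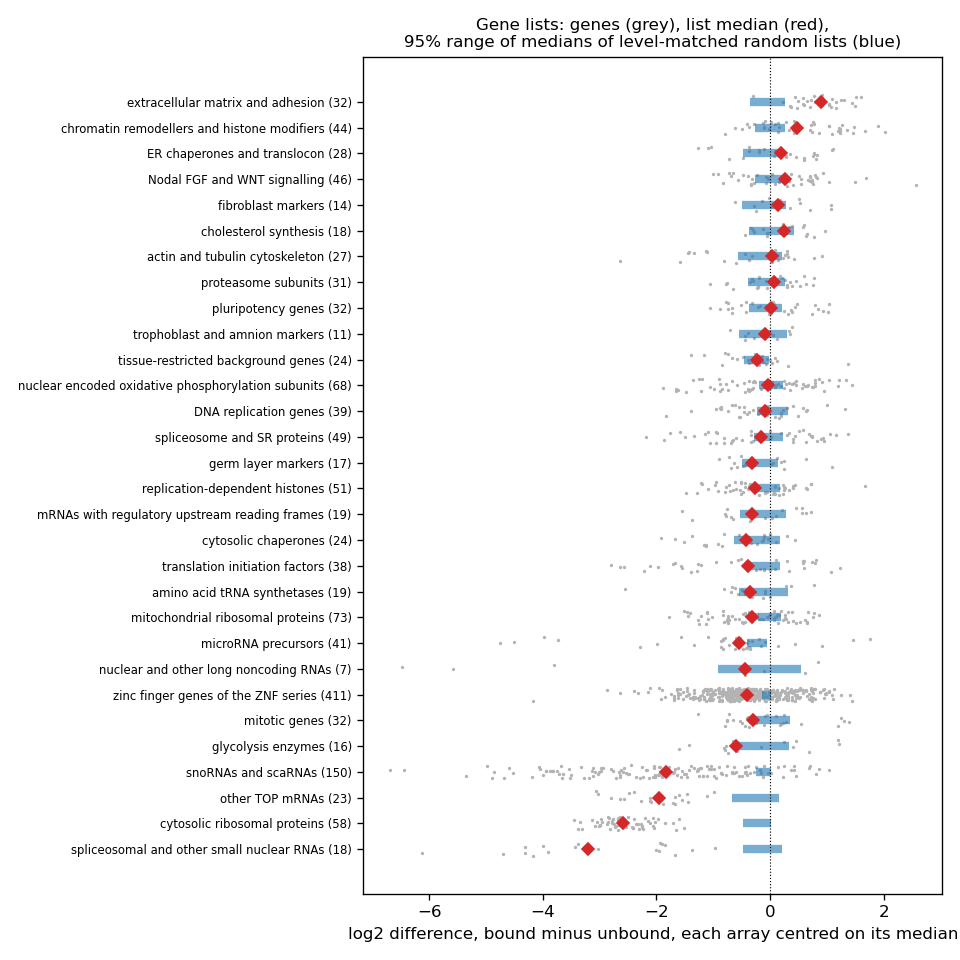
Relative log2 difference between bound and unbound RNA (horizontal axis, each array centred on its median) for the 30 gene lists with at least 5 measured genes (vertical axis, number of genes in brackets). Grey points are genes, red diamonds are list medians and blue bars span the central 95% of the medians of 10000 level-matched random lists; the lists run from small nuclear RNAs (-3.21) to extracellular matrix and adhesion (0.89), ordered by their distance from the random lists.

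Against total RNA, the bound array had mitotic and DNA replication transcripts at lower relative levels and trophoblast or amnion markers at higher ones. The genes furthest above total RNA were TTR (relative difference 3.22), APOA2 (2.82), an apolipoprotein of liver and yolk sac, ANKRD36B (2.78) and LMO3 (2.54). All of these were dim in total RNA, from 3.76 (APOA2) to 4.43 (ANKRD36B). That is above the background line of 3.75 but below the 99th percentile of background, 4.98, so their differences rest on values near background. The zinc transporter SLC30A10, at background in total RNA, was at least 13.8-fold higher in bound RNA as deposited. All of these genes were also at least 2-fold higher in unbound RNA after centring, such as TTR (1.09) and LMO3 (3.08). The furthest below were RPPH1 (-3.94), RMRP (-3.65), the secreted phosphoprotein SPP1 (-3.01), TM4SF18 (-2.99) and smooth muscle actin ACTG2 (-2.97). SPP1 (-3.53), TM4SF18 (-2.74) and ACTG2 (-2.81) were at least 2-fold lower in unbound RNA as well. Both comparisons share the total RNA array. Of 32 mitotic genes 26 were at least 2-fold lower in bound RNA after centring, with a list median of -0.28 as deposited and -1.31 after centring, and the list differed from random lists by -1.09 (percentile 0). Ribosomal protein mRNAs (-0.94, percentile 0), cytosolic chaperones (-0.77, percentile 0), DNA replication genes (-0.71, percentile 0), glycolysis enzymes (-0.71, percentile 0.02), extracellular matrix (-0.66, percentile 0) and pluripotency genes (-0.40, percentile 0) also lay below random lists. The medians of DNA replication, matrix and pluripotency genes were positive as deposited, at 0.18, 0.21 and 0.38. Trophoblast and amnion markers exceeded random lists by 0.91 (percentile 100), with TFAP2A at 1.52 and VTCN1 at 1.59, and the ZNF series by 0.18 (percentile 100). Germ layer (-0.15, percentile 12.6) and fibroblast markers (-0.20, percentile 8.42) were not set apart, except germ layer markers with no filter (-0.21, percentile 1.51). Nuclear and other long noncoding RNAs (0.03) were so with genes of 1 probe set (-0.80, percentile 0.26). In all, 2 lists lay above and 16 below, of which glycolysis (percentile 2.97) and proteasome subunits (13.1) were not set apart after lowess, nor initiation factors with the filter at the 75th percentile (5.99).

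The bound and total arrays were the most alike of the pairs, with a Pearson correlation across genes of 0.944, against 0.890 for bound and unbound and 0.901 for unbound and total, where genes are not independent replicates. As deposited, 4835 genes were at least 2-fold higher in bound than in total RNA and 69 lower (98.6% higher), against 321 and 775 after centring (29.3%), 389 and 444 after lowess (46.7%) and 395 and 409 after quantile normalization (49.1%). The extraction kit differed between total RNA and the polysome pools, so kit and source cannot be told apart in either comparison with total RNA.

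Unbound RNA was set against total RNA as the counterpart of that comparison. Transcripts with the highest relative differences were AHSA2P (4.46), the ZNF series pseudogene ZNF767P (4.05), LINC00173 (3.92) and RSRP1 (3.81). SNRPA1, at background in total RNA, was at least 13.6-fold higher in unbound RNA as deposited. AHSA2P (1.63), ZNF767P (1.18) and SNRPA1 were also at least 2-fold higher in bound RNA after centring, and LINC00173 (0.76) was not. The lowest were SPP1 (-3.53), the receptor phosphatase PTPRZ1 (-3.50), the matrix protein tenascin TNC (-3.29), ENPP1 (-3.20) and the collagen COL5A2 (-3.02). All of the lowest were at least 2-fold lower in bound RNA too, from SPP1 (-3.01) to PTPRZ1 (-1.88), and both comparisons share the total RNA array. Ribosomal protein mRNAs exceeded random lists by 1.34 (percentile 100), with 36 of 58 at least 2-fold higher and none lower after centring, and other terminal oligopyrimidine mRNAs exceeded them by 1.06 (percentile 100). SnoRNAs (1.24), small nuclear RNAs (1.26), the ZNF series (0.49) and trophoblast and amnion markers (0.76) also lay above random lists, with percentiles of 99.9 or more. Extracellular matrix genes differed from random lists by -1.45 (percentile 0), with 27 of 32 at least 2-fold lower after centring, and mitotic genes by -0.86 (percentile 0), with 22 of 32. Cholesterol synthesis (-0.71), pluripotency (-0.56), chromatin (-0.55) and DNA replication genes (-0.51) lay below random lists too, at percentiles of 0.03 or less.

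In all, 7 lists lay above random lists and 9 below. Of these, the calls were lost for mRNAs with regulatory upstream reading frames (0.43, and -0.00048 with the filter at the 75th percentile), proteasome subunits (percentile 2.90 after lowess), endoplasmic reticulum chaperones (16.7 with genes of 1 probe set) and fibroblast markers (3.09 with no filter). Glycolysis enzymes (percentile 13.7) were set apart after quantile normalization (0.71) and lowess (1.24), and nuclear and other long noncoding RNAs (93.9) with the mean of probe sets (98.2) and genes of 1 probe set (99.87). As deposited, 654 genes were at least 2-fold higher in unbound than in total RNA and 1926 lower (25.3% higher), against 974 and 1206 after centring (44.7%), 1132 and 911 after lowess (55.4%) and 885 and 1164 after quantile normalization (43.2%).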

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

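The subtraction of the bound column's constant, the 2 added ways to match random lists, the alternatives for lists in the comparisons with total RNA, and those for genes apart from total RNA in both fractions were chosen after the data were seen. Where values moved, the cause was not tested unless the alternative's construction shows it (fewer genes, another threshold). Signal near background limits the folds of dim genes. Those of genes at or below background are given as bounds, and those of genes just above it are not.

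Counts of genes at least 2-fold higher and lower are given as pairs. For bound against unbound RNA (7404 and 188) they were 1296 and 876 after quantile normalization, 767 and 1195 after centring, 769 and 1125 after lowess, 3584 and 114 with the filter at the 75th percentile, and 3454 and 94 at a 3-fold threshold, with 311 lower at 1.5-fold. For bound against total RNA (4835 and 69) they were 395 and 409, 321 and 775, 389 and 444, 1903 and 32, and 1073 and 29 in the same order, and 8840 and 170 at 1.5-fold. For unbound against total RNA (654 and 1926), the lower count was 1164 after quantile normalization and 1206 after centring. Lowess gave 1132 and 911, the 75th percentile filter 271 higher, the 1.5-fold threshold 1363 and 3947, and the 3-fold threshold 211 and 548. Genes higher and lower in both fractions than in total RNA (136 and 314) were 427 and 28 as deposited and 82 and 108 with the filter at the 75th percentile, and the lower count was 186 after quantile normalization and 186 after lowess. At the 99th percentile of background, 28 pluripotency genes were above it in total RNA, against 32, and the other counts were 6 germ layer, 4 trophoblast, 8 fibroblast and 5 background genes. With the filter at the 75th percentile the Pearson and Spearman correlations were 0.706 and 0.668 for bound and unbound, 0.862 and 0.848 for bound and total, and 0.749 and 0.679 for unbound and total RNA, and with no filter they were 0.948 and 0.958 for bound and unbound (Spearman 0.958 for unbound and total).

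List values are differences from random lists, bound minus unbound. All 30 lists kept their call after quantile normalization and after lowess. Centring takes 1 constant from every difference and cannot change these values, so it is no check on them. Matched on span, mitochondrial ribosomal proteins (-0.15), mitotic genes (-0.31), Nodal, FGF and WNT signalling (0.23) and microRNA precursors (-0.13) were no longer set apart, while glycolysis (-0.54), initiation factors (-0.34), background genes (0.21) and histones were, the last with a turned sign (0.25, from -0.19). Span-matched random lists could hold small RNAs, which lay far to the unbound side. For the short genes of the microRNA, histone and background lists these values are therefore no check on span. Mitotic genes also lost their call with no matching (-0.24) and with the list mean (-0.072), and Nodal, FGF and WNT signalling with the filter at the 75th percentile (0.11), matching on total RNA (0.24) and 100 bins (0.25). Glycolysis became set apart with no filter (-0.51), mean probe sets (-0.50), genes with 1 probe set (-0.52), matching on total RNA (-0.58) and no matching (-0.52). Initiation factors did so with matching on total RNA (-0.34) and no matching (-0.32), endoplasmic reticulum chaperones with the list mean (0.37) and 100 bins (0.37), cytosolic chaperones with no matching (-0.35) and fibroblast markers with the list mean (0.37). Long noncoding RNAs did so with no filter (-0.54), genes with 1 probe set (-2.04) and the list mean (-1.90), and background genes with no filter (-0.018).

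In unbound against total RNA, mRNAs with upstream reading frames turned from 0.43 to -0.00048 with the filter at the 75th percentile. Of the named genes at least 2-fold apart between bound and unbound RNA as deposited, those that turned sign were ACTG2 (-0.16), DNMT3B (-0.022), MALAT1 (-0.11) and TM4SF18 (-0.24) after centring, and DNMT3B (-0.078) and TM4SF18 (-0.039) after lowess. Named genes with smaller positive differences turned too after centring, among them SOX2 (-0.51), LIN28A (-0.74) and EZH2 (-0.62). Random lists without small RNAs and histones gave no value for the 4 lists of these classes, and 6 lists had no value with the filter at the 75th percentile.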

Other observations

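The comparison of both fractions with total RNA, the symbol families, the split by genomic span and the tests of array-wide offset, short mRNAs, bright probe sets, nuclear RNA loss and cell state were chosen after the results they concern were seen, while the others were written before. Gene names in this part were picked after their values were seen.

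Relative to the array medians, proliferation and some pluripotency transcripts were lower in both polysome fractions than in total RNA. After centring, 314 genes were at least 2-fold lower in both fractions, and 136 were at least 2-fold higher. Both differences share the total RNA array, so these counts may come from that array alone, and no count without change that includes this sharing is given. The balance rests on the scaling: as deposited, 28 genes were lower and 427 higher in both, and the lower count was 186 after lowess. Of 32 mitotic genes 18 were lower in both, among them TOP2A (-1.99 in bound and -2.23 in unbound RNA) and KIF20A (-2.05 and -1.69). The replicative helicase genes MCM2 (-1.72 and -1.92) and MCM4 (-1.70 and -1.60), the collagens COL4A1 (-2.28 and -2.88) and COL4A2 (-1.85 and -2.78), and the chaperones HSPA5 (-1.74 and -2.02) and HSP90AA1 (-1.82 and -1.71) were also lower in both. So were 6 of 32 pluripotency genes, GAL (-2.60 and -2.98), PRDM14 (-2.16 and -1.94), DNMT3B (-2.0 and -1.98), PODXL (-1.80 and -2.23), CD9 (-1.24 and -1.98) and L1TD1 (-1.22 and -1.27). CRIPTO (TDGF1), which was not matched to the list and is not in this count, was lower in both as well (-1.12 and -2.50). Higher in both were 2 of 11 trophoblast or amnion markers, TFAP2A (1.52 and 2.23) and VTCN1 (1.59 and 1.21). TTR (3.22 and 1.09) and APOA2 (2.82 and 2.02), both dim in total RNA, were higher in both as well. Germ layer markers went both ways: the neural regulator PAX6 was higher in both (1.72 and 2.44), as was AFP, which was at background in total RNA, while KDR (-1.54 and -1.73) and NES (-1.74 and -2.38) were lower in both.

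Among protein-coding genes, the relative difference between bound and unbound RNA was lowest for genes of short genomic span. The fifth with the shortest spans (median 5.27 kb) had a median of -0.32, with 360 genes at least 2-fold lower and 52 higher in bound RNA after centring. The fifth with the longest spans (median 174 kb) had 0.10, with 128 lower and 257 higher. The split is not matched on level and includes the ribosomal protein genes (median span 5.025 kb), all 58 of which were at least 2-fold lower after centring. It therefore does not show an effect of span itself. With random lists matched on span as well as level, the matrix list still exceeded them by 0.79 and the chromatin list by 0.37. Of 128 families of at least 10 genes that share the letters of their symbol, 9 lay below and 14 above level-matched random lists. With span matched 7 and 9 did so, among those above the KRTAP family (0.38) of the background list. Independent random families would give 6.4 in all. That is no fair baseline, because RPL, RPS, ZNF and MRPL consist largely of genes in fixed lists already found below, and related genes are not independent draws. Outside the fixed lists, THAP genes (-0.53, and -0.42 with span matched) lay below and the claudins of the CLDN family (0.46, and 0.64 with span matched) above. The EXOSC genes of the RNA exosome (-0.65) and the SEMA (0.50) and GALNT (0.62) families, the semaphorins and the enzymes that start mucin-type glycosylation, were set apart with level matched and no longer with span matched (percentiles 4.19, 96.7 and 97.4). Of 6148 probe sets past the filter that are not listed with a gene, 301 were at least 2-fold higher and 1372 lower in bound RNA after centring. These counts are not matched on level. Background genes were higher on the bound array by a median of 0.71, less than the 1.26 that centring removes, so dim probe sets lean to the unbound side through the scaling.

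The one-sided split between bound and unbound RNA is the first pattern weighed. An exchange of the bound and unbound labels is argued against by the snoRNAs, which differed from random lists by -1.72 toward the unbound side. An exchange that involves the total RNA label was not tested. An array-wide offset cannot be told apart from a shift of most transcripts by these counts: 7592 genes were 2-fold apart as deposited and 1962 after centring, of which 39.1% were higher in bound RNA (46.8% with the median difference removed), but centring itself pulls that balance towards even. The 480 background genes were also higher on the bound array, by a median of 0.71 against the offset of 1.26. At background signal the arrays thus differ without a shift of expressed transcripts, and how much of the 1.26 is of this kind stays open. Removal of the lowess trend left 1894 genes, which met the prediction for an intensity-dependent distortion, but centring alone did as much, so this test cannot separate the explanations. Total RNA lay between the fractions for 68.8% of the genes apart after centring, above the 33.3% predicted for random order, but shuffled totals gave a mean of 78.8%, and as deposited the share was 82.9% against 79.5%, so that baseline was wrong, the scalings disagree and whether the arrays come from 1 RNA pool stays open.

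Ribosomal protein and other terminal oligopyrimidine mRNAs on the unbound side are the second pattern. Genomic span as the cause is argued against by the list's distance from span-matched random lists, -2.19 (percentile 0), and compression of bright signals by -1.81 after lowess (percentile 0). As a class of short mRNAs, oxidative phosphorylation subunits and mitochondrial ribosomal proteins would need a like shift, and the lower of these lists reached -0.31. The length of the mRNA itself was not analysed here, and short reading frames hold fewer ribosomes, so monosome or light polysome association stays open. No biological explanation was tested for this pattern.

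In the third pattern, the shared direction of both fractions against total RNA, mitotic genes differed from random lists by -1.04 in the mean of the fractions, and by -1.04 with genomic span matched (percentile 0), while trophoblast and amnion markers exceeded span-matched lists by 0.76 (percentile 100). For these lists the values argue against genomic span as the cause. The length of the mRNA was not analysed for this pattern either, so it stays open. Nuclear RNA loss is undecided: the 7 nuclear and other long noncoding RNAs exceeded random lists by 0.17 (percentile 78.3), too few to settle it, and with genes of 1 probe set the fractions went apart (-0.80 in bound and 1.18 in unbound RNA). SnoRNAs exceeded them by 0.34, which taken alone would argue against it; they were the list first used for this test and were replaced once both values were seen, since the column kits may differ in their yield of short RNAs. Another cell state in the culture behind the fractions stays open: pluripotency and trophoblast genes are part of the pattern and cannot test it. Germ layer markers, which share HAND1 with the trophoblast list, were within random lists (-0.16, percentile 8.50) and went both ways. Fibroblast markers lay below random lists (-0.33, percentile 0.83). They share COL1A1, COL1A2 and COL3A1 with the matrix list, so they are not independent of the pattern. Extraction kit and array are each bound to the source of the RNA, so these cannot be separated here. Whether the fractions and total RNA came from the same culture is not given.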
